A study of Penicillium oxalicum with 15 samples.

How the data were processed

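RNA was measured in mycelia of the filamentous fungus Penicillium oxalicum, which secretes cellulose-degrading enzymes. Per the labels, 3 strains were used: the reference strain M12, the strain gClrBID, which overexpresses an internal mutant of the transcription factor ClrB, and a creA deletion strain. Mycelia were grown for 22 h on 2% glucose in Vogel's medium and then moved for 4 h to 2% (w/v) glucose or cellulose, at 30 °C and 200 rpm. The libraries were stranded mRNA libraries, per the labels' protocols. The 15 libraries form 5 groups of 3, and the series text calls them biological triplicates without describing the cultures further, so p-values measure the spread between these libraries. The creA deletion strain on glucose was not analysed here.

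The authors deposited 1 table of FPKM values, fragments scaled by gene length and by the counted total of the library, for 9976 genes. Its 15 value columns carry the sample titles, and each was assigned to its sample by that title. Per the submitters' processing notes, CASAVA 1.8, HISAT2 2.0.0, featureCounts 1.5.0-p1 and DESeq2 were used, with no roles or order stated. The genome build, the annotation and the strand setting of the counting were not given in the sources used here. Fragments shared between near-identical or overlapping genes could therefore not be assessed. Of the gene identifiers, 187 were at 0 in all libraries.

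None of the identifiers could be named from the reference table used here, the RefSeq gene list of strain HP7-1 (assembly ASM172317v3), in which 0 of the 9976 identifiers matched. The deposited table does not pair identifiers with names. Names are printed for 15 locus tags whose identity in strain 114-2 was fixed from prior knowledge of the species before the data were examined: clrB (PDE_05999), creA (PDE_03168), xlnR (PDE_07674), amyR (PDE_03964), brlA (PDE_00087), cel7A-2 (PDE_07945), cel7B (PDE_07929), cel6A (PDE_07124), cel5B (PDE_09226), cel61A (PDE_05633), bgl2 (PDE_00579), xyn10A (PDE_08094), amy15A (PDE_09417), amy13A (PDE_01201) and cdtC (PDE_00607). PDE_02736, placed in the beta-glucosidase list, is given by its tag, which makes 16 genes fixed in advance. The tag of creA was checked by its loss in the deletion strain and that of clrB by its level in gClrBID on glucose, whereas on cellulose clrB was lower in gClrBID than in M12. The other names were not checked by a value or a sequence. Further gene lists had been planned from product descriptions, and since none came with the identifiers these lists had no members, or only 1 of the tags above, and were not tested. The lists tested were cellulases (5 genes: cel7A-2, cel7B, cel6A, cel5B and cel61A), beta-glucosidases (2: bgl2 and PDE_02736), amylolytic enzymes (2: amy15A and amy13A) and zinc cluster transcription factors (2: clrB and xlnR). amyR also encodes a zinc cluster factor and was fixed as a single gene outside that list. The planned rule also ranked the 12 highest and 12 lowest fold changes in the first 4 comparisons, and 5 and 5 in the others. The ranked genes had to be called, reach a mean of 10 FPKM in the higher group and show no overlap between replicates. Of these only a few identifiers are printed, because they carry no names.

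Fold changes were estimated on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3. The model had 1 mean per group over all 15 libraries, 8 contrasts and moderated variances with an intensity trend. A gene was tested if it reached 1 FPKM in at least 3 libraries, which left 8765 genes. Genes with a Benjamini-Hochberg adjusted p under 0.05 are described as called. Every adjusted p in the text comes from limma unless another test is named, and fold changes on this scale understate those of genes near 0. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01 and again with an estimated one, adjusted over all lists and contrasts. The model was tested on simulated data. In the comparison of gClrBID with M12 on glucose it recovered 99% of 100 genes changed 2-fold and 88% of 100 changed 1.5-fold among 8762 genes, with 18 unchanged genes called. The simulated changes were few, balanced in direction and placed in genes above a minimum of expected fragments. The number of unchanged genes called therefore need not hold where most genes shifted. The choice of limma on log values had been planned for the case that the table held no counts, which it did not.

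Depth was worked back from the table, since FPKM values of 1 gene are whole multiples of the worth of 1 fragment. With a tolerance of 5e-05 FPKM, the values of all 9789 genes above 0 came out as whole fragments. Before a common factor was removed, the totals were 3.0 times the summed fragments. Gene lengths were then searched only among multiples of 3, so that all were multiples of 3 is by construction. They were read as coding length on the factor of 3.0 alone. The recovered totals lay between 10129674 and 18361208 fragments per library and differed from the sums of the fragments by at most 3. On simulated data for 9976 genes, 99.97% of values were recovered exactly. The fragments were used for depth, for shares of fragments, for the floor of 3 fragments per library and for alternatives chosen after the data were seen. Statements on the floor cover counting error only.

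The alternatives planned were a pseudocount of 0.1, no filter on low values, a minimum of 5 FPKM, median-of-ratios scaling, rescaling to TPM, a fit of only the groups compared, a replicate block, robust moderation, an estimated inter-gene correlation, other fold minimums and leaving out each library in turn. Limma with voom weights on the recovered fragments, with and without median-of-ratios scaling, was added after the data were seen. Comparisons against the same 3 control libraries were set beside 50 simulations of unchanged groups and the overlap of independent lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for the fragments, the further tests and the plots.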

Results

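The transcriptomes of 3 strains of P. oxalicum were compared, with M12 as the control and 3 libraries in each of 5 groups. M12 and gClrBID were measured on glucose and on cellulose, and the creA deletion strain on cellulose. The libraries held 15158030 to 17911045 fragments for M12 on glucose, 10129672 to 13427079 for gClrBID on glucose and 13621129 to 15930698 for M12 on cellulose. They held 13482301 to 15267426 for gClrBID and 14715236 to 18361206 for the creA deletion on cellulose. Pearson's r between replicates, across genes of log values, lay between 0.992 and 0.997. The spread between replicates was not equal in all groups. Squared differences in fragments between replicates, per gene and relative to counting error, ranged from 3.21 to 22.3. They were highest on cellulose, between replicates 1 and 3 of gClrBID (22.3) and of the creA deletion (15.8).

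The genes altered in the strains were examined first. creA, which encodes the repressor of carbon catabolite repression, stood at 0.1048, 0.0542 and 0 FPKM in the 3 libraries of the deletion strain, from 2, 1 and 0 fragments. It stood at 434 ± 33.9 FPKM (SD, n = 3) in M12 on cellulose. clrB, which encodes an activator of cellulase genes, reached 469 ± 16.4 FPKM in gClrBID on glucose against 10.1 ± 0.345 in M12 (SD, n = 3 each), 46.7 times as much. On cellulose clrB was lower in gClrBID, at 73.7 ± 16.5 FPKM, than in M12, at 153 ± 6.43 (SD, n = 3 each), with a log2 fold change of -1.06 ± 0.11 (SE) and an adjusted p of 6.6e-07. The 3 gClrBID libraries on cellulose were each below the lowest M12 library.

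**Figure D1:**
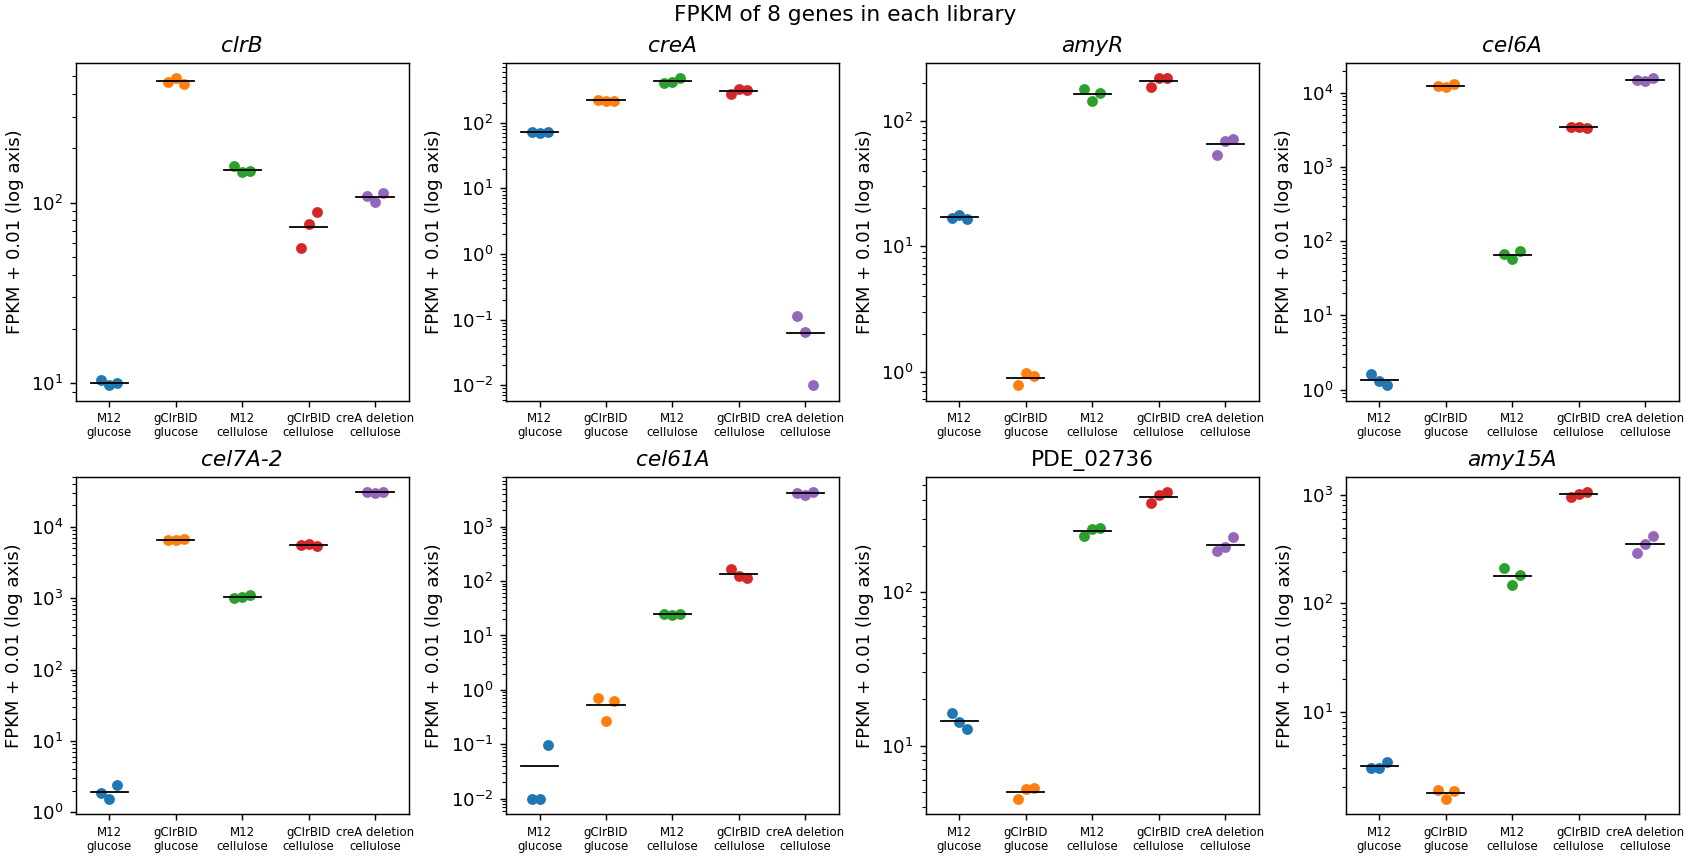
FPKM (log axis, 0.01 added so that values of 0 can be drawn) of 8 genes in each of the 15 libraries; points are libraries, lines are group means, and the groups are the strain and carbon source. clrB peaked in gClrBID on glucose at 469 FPKM, while cel61A stood at 0.523 FPKM in that group and at 4074 FPKM in the creA deletion on cellulose.

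The response of the reference strain to cellulose was measured against glucose. All 16 genes fixed in advance rose on cellulose. The transporter gene cdtC, for cellodextrins, rose by 8.63 ± 0.07 and the cellobiohydrolase gene cel7A-2 by 8.49 ± 0.08 on the log2 scale (SE, n = 3 per group), from 1.93 ± 0.447 to 1046 ± 57.5 FPKM for cel7A-2. All 5 cellulase genes rose: the cellobiohydrolase gene cel6A by 4.83 ± 0.08, the endoglucanase genes cel7B and cel5B by 5.25 ± 0.06 and 5.93 ± 0.13, and cel61A, for a lytic polysaccharide monooxygenase, from 0 or 1 fragments per library to 24.5 ± 0.481 FPKM (SD). Among the regulators, clrB rose by 3.80 ± 0.11, brlA, a regulator of conidiation, by 3.62 ± 0.15, amyR, an activator of amylase genes, by 3.18 ± 0.10, creA by 2.59 ± 0.07 and xlnR, an activator of xylanase genes, by 1.65 ± 0.05. The amylolytic genes amy15A, for a glucoamylase, and amy13A, for an alpha-amylase, rose by 5.44 ± 0.12 and 3.59 ± 0.15. As a list, the cellulases moved up against all other genes (adjusted p = 0.0013, and 0.046 with an estimated correlation). The amylolytic (0.092), beta-glucosidase (0.060) and zinc cluster (0.091) lists did not pass as lists, although both members of each rose. The beta-glucosidase list passed without a filter on low values (adjusted p = 0.0473, and 0.0473 to 0.229 over all alternatives).

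Over all tested genes, 3622 were higher and 3753 lower on cellulose in M12, of which 1927 and 1660 changed at least 2-fold, and median-of-ratios scaling turned the balance to 3739 higher and 3604 lower. Without a name in the sources used here, PDE_06609 rose by 9.21 and PDE_03140 fell by 7.48. Of the 16 fixed genes, 16 rose also when adjusted over the list alone.

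The effect of the ClrB mutant without cellulose was measured in glucose cultures. All 5 cellulase genes were called higher in gClrBID than in M12. cel6A rose from 1.35 ± 0.256 to 12569 ± 660 FPKM, a log2 fold change of 12.39 ± 0.08 (SE) with an adjusted p of 3.1e-22. cel5B and cel7B rose by 11.98 ± 0.13 and 8.73 ± 0.06, cel7A-2 by 11.15 ± 0.08, the xylanase gene xyn10A by 10.43 ± 0.09, cdtC by 9.89 ± 0.07 and the beta-glucosidase gene bgl2 by 9.17 ± 0.06 (SE, n = 3 per group). Together the fixed enzyme genes, the transporter gene cdtC not counted, held 6.18 ± 0.236% of the fragments in gClrBID and 0.00832 ± 0.000457% in M12.

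Other genes that rose on cellulose in M12 stayed low or fell in gClrBID on glucose. cel61A was called higher (adjusted p = 0.0010), at 0.523 ± 0.229 FPKM, on 2 to 7 fragments per gClrBID library against 0 or 1 in M12. PDE_02736 fell by 1.37 ± 0.09 and amyR fell by 3.26 ± 0.10, from 17.0 ± 0.784 to 0.882 ± 0.102 FPKM. amy13A fell by 0.69 ± 0.15 and amy15A by 0.58 ± 0.12, both from a few FPKM at most, and the call of amy15A was lost with voom weights on the fragments (adjusted p = 0.0885, and 7.2e-05 to 0.267 over all alternatives). creA rose by 1.60 ± 0.07 and xlnR by 0.39 ± 0.05, while brlA stood at 2.51 ± 0.564 and 2.64 ± 0.652 FPKM in M12 and gClrBID (adjusted p = 0.798). Of the 16 fixed genes 11 rose, 4 fell and 1 was not called, with the same numbers adjusted over the list alone. The cellulases moved up as a list (adjusted p = 3.4e-08, and 0.0064 with an estimated correlation). The zinc cluster list passed at the preset correlation (adjusted p = 0.0074) and not with an estimated correlation (adjusted p = 0.11). Its 2 members were clrB, overexpressed by construction (5.41), and xlnR (0.39), while amyR, a zinc cluster factor outside the list, fell. The beta-glucosidases (0.256) and amylolytic enzymes (0.696) did not pass.

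In glucose 1493 genes were higher and 4797 lower in gClrBID, of which 429 and 1342 changed at least 2-fold. Median-of-ratios scaling moved the median log2 fold change of all tested genes by 0.26, from -0.26, and the split to 2977 higher and 2916 lower. PDE_00503 fell by 9.95 and PDE_09959 fell by 9.34.

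**Figure D2:**
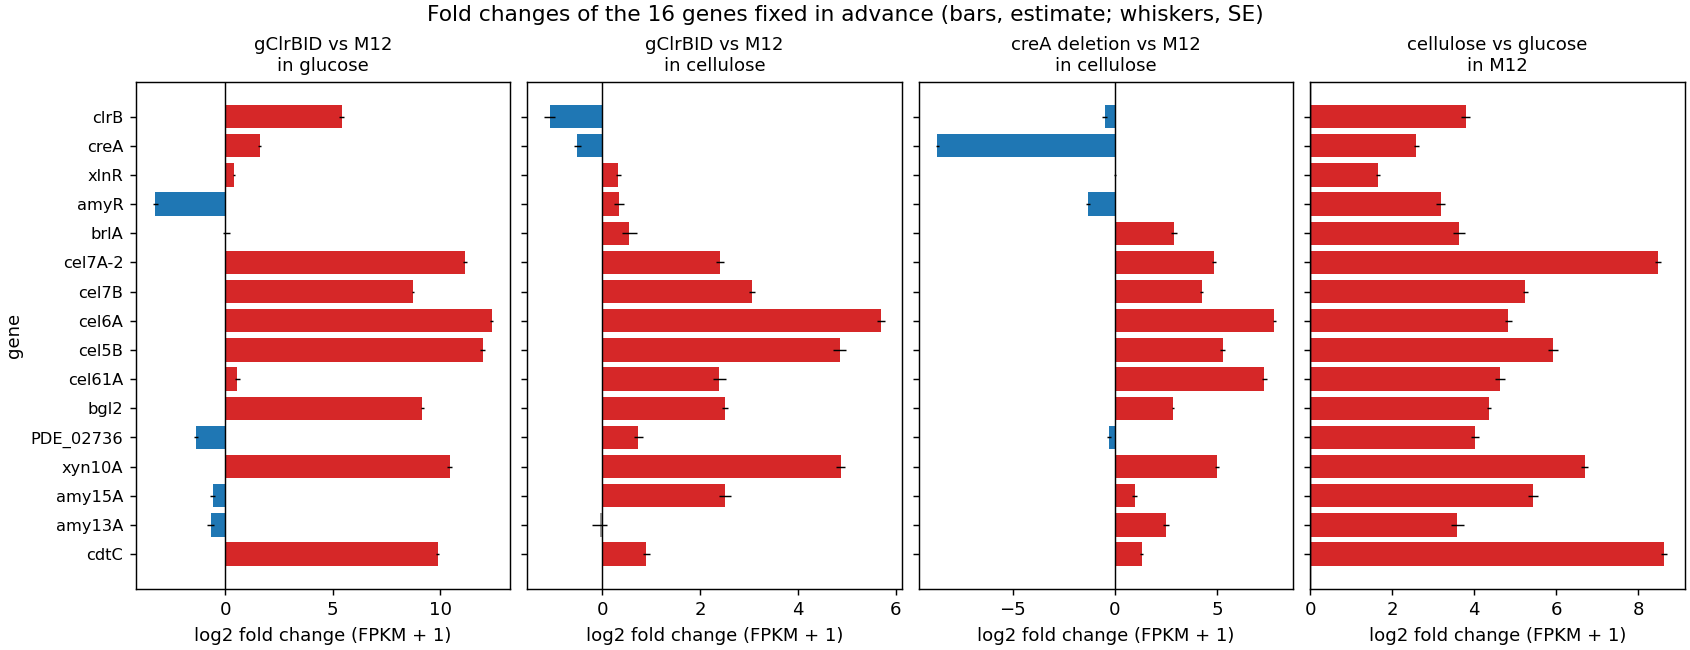
Log2 fold changes on the FPKM + 1 scale (horizontal axes, each with its own range) of the 16 genes fixed in advance (vertical axis) in 4 comparisons; bars are limma estimates, whiskers are SE, red bars are called higher, blue bars called lower and grey bars not called. The bar of cel6A reaches 12.39 in glucose. The lengths of the bars of creA in the deletion strain and of cel61A against M12 on glucose rest on 0 to 2 fragments per library in the lower group and depend on the pseudocount, and the small bar of PDE_02736 in the creA deletion turns to 0.02 after median-of-ratios scaling.

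Levels in gClrBID on glucose were then set against those of M12 on cellulose, the inducing condition. 4 of the 5 cellulase genes were higher without cellulose in gClrBID than with it in M12: cel6A by 7.56 ± 0.08, cel5B by 6.05 ± 0.13, cel7B by 3.48 ± 0.06 and cel7A-2 by 2.66 ± 0.08 (log2, SE, n = 3 per group). bgl2, xyn10A and cdtC were higher by 4.81 ± 0.06, 3.74 ± 0.09 and 1.26 ± 0.07. cel61A was lower by a log2 fold change of -4.08 ± 0.13, and amyR, amy15A, PDE_02736 and amy13A by -6.44, -6.02, -5.39 and -4.28. The cellulase list passed at the preset correlation (adjusted p = 0.030) and not with an estimated correlation (adjusted p = 0.147) or after median-of-ratios scaling (adjusted p = 0.0715, and 0.0235 to 0.147 over all alternatives). The amylolytic enzymes (0.144), beta-glucosidases (0.881) and zinc cluster factors (0.953) did not pass.

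Of the 1927 genes that rose at least 2-fold on cellulose in M12, 203 (10.5%) rose at least 2-fold and 393 (20.4%) fell at least 2-fold in gClrBID on glucose. Of the 6838 other tested genes, 226 (3.3%) rose and 949 (13.9%) fell at least 2-fold. Of the induced genes 73 were higher in gClrBID on glucose than in M12 on cellulose and 1829 lower. The induced genes were picked for higher values in the same M12 cellulose libraries. A gene that gClrBID left unmoved on glucose is lower by that choice, so the count of 1829 does not measure an effect of gClrBID. The count of 393 became 608 with a pseudocount of 0.1 and 594 with voom weights, and that of 203 became 351 with voom weights and median-of-ratios scaling. Over all genes 3034 were higher and 4526 lower in gClrBID on glucose than in M12 on cellulose, with a shift of the median by 0.225 under median-of-ratios scaling and a split of 3670 and 3914.

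Because the comparison of gClrBID with M12 on glucose and that of cellulose with glucose in M12 share the M12 glucose libraries, their overlap was set beside simulated and independent values. The same genes were called higher in both in 758 cases and lower in both in 2186, with 617 and 2054 for independent lists. Opposite calls numbered 2453, against 2622 for independent lists. Median-of-ratios scaling changed the shared calls to 1260 higher and 1180 lower. At a minimum of 2-fold, 203 were higher in both, 422 lower in both and 429 opposite, with 94.3, 254 and 376 for independent lists, so that opposite calls then exceeded that value. The correlation of fold changes across genes was 0.248, with 0.50 simulated for unchanged groups, and the covariance was 0.469, with 0.00715 simulated. The simulated covariance is what the shared controls add. No split of the 3 control libraries leaves 2 in each part, so part of the excess of shared calls may come from the shared controls, and genes are not independent replicates.

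The carbon response was also measured within gClrBID. Here 4 of the 5 cellulase genes were lower on cellulose than on glucose: cel6A fell by 1.87 ± 0.08, cel5B by 1.20 ± 0.13, cel7B by 0.42 ± 0.06 and cel7A-2 by 0.25 ± 0.08 on the log2 scale (SE, n = 3 per group), the last not called after rescaling to TPM (adjusted p = 0.147, and 1.6e-06 to 0.147 over all alternatives). clrB fell by 2.68 ± 0.11 and bgl2 by 2.30 ± 0.06. cel61A rose by 6.47 ± 0.13, from 0.523 ± 0.229 to 135 ± 30.1 FPKM, amyR by 6.79 ± 0.10, amy15A by 8.53 ± 0.12 and PDE_02736 by 6.13 ± 0.09. No list passed: the adjusted p was 0.281 for cellulases, 0.101 for amylolytic enzymes, and 0.953 for both beta-glucosidases and zinc cluster factors. On cellulose 4332 genes were higher and 3003 lower than on glucose, and median-of-ratios scaling moved the median by -0.173 and the split to 3768 and 3617.

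Whether the strain effect differed between carbon sources was tested as an interaction, the gClrBID effect on cellulose minus that on glucose. The effect was smaller on cellulose for cdtC (-8.98 ± 0.10), cel7A-2 (-8.74 ± 0.11), cel5B (-7.13 ± 0.18), cel6A (-6.70 ± 0.12), bgl2 (-6.66 ± 0.08), cel7B (-5.68 ± 0.08) and xyn10A (-5.56 ± 0.13), all log2 with SE and n = 3 per group. The interaction is also the carbon response of gClrBID minus that of M12, so the rise of these genes on cellulose in M12 enters it. For clrB itself it was -6.48. The values therefore do not by themselves show a weaker action of the mutant on cellulose. The strain effect was more positive on cellulose for amyR (3.60 ± 0.15), amy15A (3.09 ± 0.18) and PDE_02736 (2.10 ± 0.13). The cellulases moved down as a list (adjusted p = 6.9e-05, and 0.018 with an estimated correlation). The zinc cluster (0.066, and 0.0499 without gClrBID cellulose replicate 1), amylolytic (0.284) and beta-glucosidase (0.423) lists did not pass. For cel61A (PDE_05633), near the floor on glucose, the interaction of 1.84 ± 0.18 was not called with a pseudocount of 0.1 (0.18) and turned to -0.88 with voom weights on the fragments. For brlA the interaction of 0.51 (adjusted p = 0.045) was lost under most alternatives, among them median-of-ratios scaling (adjusted p = 0.168, and 0.0139 to 0.583 over all alternatives). It was also lost without M12 glucose replicate 1 (0.0833) or 3 (0.116), gClrBID glucose replicate 1 (0.126), M12 cellulose replicate 1 (0.122) or 2 (0.0725), or gClrBID cellulose replicate 1 (0.0690) or 2 (0.0879).

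An interaction was called for 5972 genes, 4208 with a more positive and 1764 with a more negative effect on cellulose. Median-of-ratios scaling moved the median by -0.218 and the split to 2918 and 2614.

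The effect of the ClrB mutant under inducing conditions was measured on cellulose. All 5 cellulase genes rose above M12: cel6A by 5.69 ± 0.08, to 3445 ± 98.9 from 66.0 ± 7.45 FPKM, cel5B by 4.85 ± 0.13, cel7B by 3.06 ± 0.06, cel7A-2 by 2.41 ± 0.08 and cel61A by 2.39 ± 0.13 (log2, SE, n = 3 per group). xyn10A rose by 4.87 ± 0.09, bgl2 by 2.51 ± 0.06, amy15A by 2.51 ± 0.12, cdtC by 0.90 ± 0.07 and PDE_02736 by 0.74 ± 0.09. creA fell by 0.50 ± 0.07. brlA rose by 0.56 ± 0.15, xlnR by 0.33 ± 0.05 and amyR by 0.34 ± 0.10, the last not called without M12 cellulose replicate 2 (adjusted p = 0.0646, and 0.0011 to 0.0646 over all alternatives). amy13A stood at 22.6 ± 2.87 and 22.0 ± 3.87 FPKM in M12 and gClrBID (SD, n = 3 each, adjusted p = 0.828). Of the 16 fixed genes 13 rose, 2 fell and 1 was not called, with the same numbers adjusted over the list alone.

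The cellulases moved up as a list (adjusted p = 8.6e-07, and 0.0080 with an estimated correlation). The beta-glucosidases passed at the preset correlation (adjusted p = 0.019) and not with an estimated correlation (adjusted p = 0.147), and the amylolytic (0.249) and zinc cluster (0.979) lists did not pass. On cellulose 2394 genes were higher and 2816 lower in gClrBID, of which 371 and 501 changed at least 2-fold, and median-of-ratios scaling turned the balance to 2863 higher and 2425 lower. PDE_03926 rose by 5.87, and PDE_05338 fell by 8.10.

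The effect of losing creA was measured on cellulose. All 5 cellulase genes rose: cel6A by 7.81 ± 0.08, to 15004 ± 713 FPKM, cel61A by 7.32 ± 0.13, cel5B by 5.28 ± 0.13, cel7A-2 by 4.86 ± 0.08, to 30272 ± 493 FPKM, and cel7B by 4.25 ± 0.06 (log2, SE, n = 3 per group). xyn10A rose by 5.02 ± 0.09, bgl2 by 2.85 ± 0.06, amy13A by 2.50 ± 0.15, cdtC by 1.31 ± 0.07 and amy15A by 0.97 ± 0.12. The fixed enzyme genes, again without cdtC, held 10.3 ± 0.289% of the fragments, against 0.417 ± 0.0151% in M12. brlA rose by 2.88 ± 0.15, from 42.3 ± 7.51 to 317 ± 40.5 FPKM, while amyR fell by 1.33 ± 0.10. Smaller differences changed with the scaling: clrB fell by 0.50 ± 0.11 and was not called after median-of-ratios scaling (-0.18), PDE_02736 fell by 0.30 ± 0.09 and turned to 0.02 (not called either without creA deletion replicate 1, adjusted p = 0.0521, and 0.0015 to 0.845 over all alternatives), and xlnR stood at 0.01 ± 0.05 and was called higher by 0.32.

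As a list the cellulases moved up (adjusted p = 7.9e-08, and 0.0064 with an estimated correlation). The amylolytic enzymes passed at the preset correlation (adjusted p = 0.032) and not with an estimated correlation (adjusted p = 0.229), a pseudocount of 0.1 (adjusted p = 0.0738) or median-of-ratios scaling (adjusted p = 0.0936, and 0.0247 to 0.229 over all alternatives). The beta-glucosidases (0.197) and zinc cluster factors (0.999) did not pass. Of the 16 fixed genes 11 rose, 4 fell, creA among them, and 1 was not called, with the same numbers adjusted over the list alone. Over all genes 1860 were higher and 4751 lower in the deletion strain, of which 475 and 1236 changed at least 2-fold. Median-of-ratios scaling moved the median by 0.28, from -0.28, and the split to 3208 higher and 3078 lower, or 717 and 738 at a minimum of 2-fold. PDE_07091 rose by 7.88, and PDE_04915 fell by 4.55.

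The 2 altered strains were compared directly on cellulose. cel61A was lower in gClrBID than in the creA deletion by a log2 fold change of -4.92 ± 0.13, cel7A-2 by -2.45 ± 0.08, cel6A by -2.12 ± 0.08 and cel7B by -1.19 ± 0.06 (SE, n = 3 per group). cel5B was lower by -0.43 ± 0.13, a call lost with a pseudocount of 0.1 (adjusted p = 0.087, and 6.0e-08 to 0.087 over all alternatives). amy13A and brlA were lower in gClrBID by -2.54 ± 0.15 and -2.32 ± 0.15, while amyR, amy15A and PDE_02736 were higher by 1.67 ± 0.10, 1.54 ± 0.12 and 1.04 ± 0.09. xyn10A stood at 8499 ± 626 and 9375 ± 433 FPKM (adjusted p = 0.187) and was called lower in gClrBID after median-of-ratios scaling (-0.41). The cellulases moved down as a list (adjusted p = 2.2e-05, and 0.015 with an estimated correlation). The amylolytic (0.696), zinc cluster (0.867) and beta-glucosidase (0.942) lists did not pass. Over all genes 4412 were higher and 1737 lower in gClrBID, and median-of-ratios scaling moved the median by -0.236 and the split to 2752 and 3136.

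Both strain effects on cellulose were measured against the same 3 M12 libraries. The calls shared between them numbered 1027 higher in both and 2241 lower in both, against 508 and 1526 for independent lists, and 1009 were opposite, against 1895. Median-of-ratios scaling changed the number higher in both to 1718. Across genes the correlation of fold changes was 0.343, with 0.50 simulated for unchanged groups, and the covariance was 0.237, with 0.00715 simulated. At a minimum of 2-fold, 104 genes were higher in both, 303 lower in both and 111 opposite, with 20.1, 70.6 and 79.5 for independent lists, so that opposite calls then exceeded that value. The simulated value is again the covariance that the shared controls add, while part of the excess of shared calls may come from them.

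**Figure D3:**
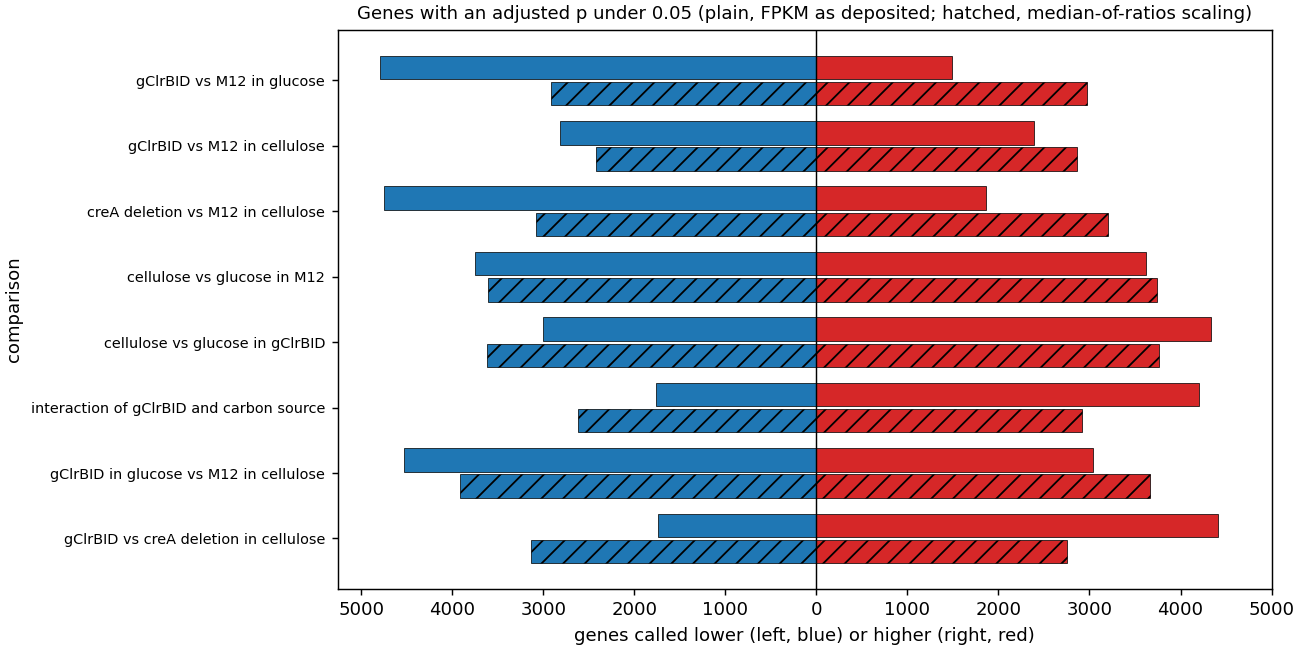
Number of genes with an adjusted p under 0.05 (horizontal axis) called lower (left, blue) or higher (right, red) in each of the 8 comparisons (vertical axis); plain bars use FPKM as deposited and hatched bars FPKM after median-of-ratios scaling. For gClrBID on glucose the bars change from 1493 higher and 4797 lower to 2977 and 2916.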

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

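The tests of scaling, exchanged labels, the resident gene, the most abundant genes and other splits of the libraries were chosen after the results they test had been seen; those of gene length, of redistribution and of CreA were written down before. Groups of 3 libraries were not examined for outliers. Of the genes with a called interaction, 1566 were called in opposite directions on the 2 carbon sources. They were counted on FPKM as deposited, with a median log2 fold change of -0.26 on glucose, and not recounted after median-of-ratios scaling. At a minimum of 2-fold, 27 genes rose on glucose and fell on cellulose, and 71 did the opposite. Numbers for independent lists were not computed for these counts. The counts therefore do not show more opposite calls than unrelated effects would give. In total the strain effect of gClrBID differed between cellulose and glucose for 5972 genes by the interaction test. Among the fixed genes the difference was -8.98 for cdtC (PDE_00607), -8.74 for cel7A-2 (PDE_07945), -7.13 for cel5B (PDE_09226), -6.70 for cel6A (PDE_07124), -6.66 for bgl2 (PDE_00579), -6.48 for clrB (PDE_05999), -5.68 for cel7B (PDE_07929), -5.56 for xyn10A (PDE_08094) and -2.10 for creA (PDE_03168). It was 3.60 for amyR (PDE_03964), 3.09 for amy15A (PDE_09417), 2.10 for PDE_02736, 1.84 for cel61A (PDE_05633), 0.64 for amy13A (PDE_01201) and 0.51 for brlA (PDE_00087), the last lost under most alternatives and that of cel61A turned to -0.88 with voom weights.

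Other splits of the same libraries were tried for each comparison. The 10 splits of 3 against 3 are too few for a share under 0.05, and in each of the 7 comparisons of 2 groups 1 of the 10 splits, the real one, gave as many genes. The real and the highest other counts were 6290 and 0 for gClrBID on glucose, 5210 and 1 for gClrBID on cellulose, 6611 and 0 for the creA deletion, 7375 and 0 for cellulose in M12, 7335 and 0 for cellulose in gClrBID, 7560 and 0 for gClrBID on glucose against M12 on cellulose, and 6149 and 0 for gClrBID against the creA deletion. For the interaction 2 of 100 splits gave as many genes as the real count of 5972. The other one, with 6156 genes, exchanged all strain labels within cellulose, which turns the difference of the strain effects into their sum, and the next highest gave 4096. Exchanging strain labels within a carbon source removes the strain effects and not only their difference, so these splits do not decide whether chance gives the interaction.

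clrB was lower in gClrBID than in M12 on cellulose, although the strain overexpresses a mutant of it and its cellulase genes were higher. Scaling is argued against by a log2 fold change of -1.01 after median-of-ratios scaling. An exchange of some of the labels is argued against by 0 of the 3 gClrBID libraries with cel6A below 2 times the highest M12 library. This count cannot detect an exchange of all labels between the 2 groups, which would leave it the same. A resident clrB gene transcribed on cellulose as in M12 would keep clrB at or above the M12 level. The highest gClrBID library minus the lowest M12 library was -59.4 FPKM. This restates the lower level that is to be explained, so the outcome was fixed in advance and is no separate evidence on such a gene. Nor does it decide about a resident gene transcribed less than in M12, and whether gClrBID keeps a resident gene was not examined. The loss of fragments at sequence changed in the mutant stays open. The level on glucose was 6.37 times that on cellulose, and no values per part of the gene were used here. That the introduced gene is less transcribed on cellulose, or that the mutant lowers the resident gene, may also account for it and was not tested.

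Most genes had lower FPKM in gClrBID on glucose and in the creA deletion on cellulose. Gene length is argued against, since the highest median log2 fold change in any of 3 length classes was -0.249. Leaving out the genes among the 20 most abundant of any library moved the median in glucose from -0.26 to -0.159 and in the creA deletion from -0.28 to -0.06, so a share taken by these genes may account for part of it and cannot be told apart from the rest. Redistribution of a fixed total toward the genes that rose at least 2-fold predicted -0.24 against an observed -0.29 in glucose, but -0.50 against -0.32 in the creA deletion, a miss of 0.183 against the 0.1 set beforehand. Since the genes were picked by their change and the rest lose that share by arithmetic, the miss decides nothing, and redistribution and a lower transcript level of most genes both stay open.

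A large part of the cellulose-induced genes did not rise at least 2-fold in gClrBID on glucose. The hypothesis that CreA holds them down predicted that the creA deletion would raise them more than the induced genes that did rise. On cellulose the opposite was found for the medians. The median log2 fold change in the deletion was -0.71 for the 1724 genes that did not rise and -0.09 for the 203 that did. The difference was -0.63 (permutation of genes, p = 1e-04, the smallest that 10000 permutations can give). Members of both sets went both ways. Of the 1724 genes, 163 (9.5%) rose and 623 (36.1%) fell at least 2-fold in the deletion. Of the 203 genes 53 rose and 53 fell, and of all tested genes 5.4% rose and 14.1% fell. The medians compare whole sets, so they cannot decide whether CreA holds down part of the 1724 genes. Genes are not independent replicates. The deletion on glucose was not analysed here, so the test bears on CreA in cellulose cultures only.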

How the results depend on the processing

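The voom fits on recovered fragments were added after the data were seen, and all other alternatives were planned. Over all alternatives, 611 results on counts of genes stayed within 1.5 times their value and 33 did not. Leaving out each library in turn kept every count between 0.845 and 1.05 times its value. Of the fixed-gene results 2121 kept direction and side of the threshold, 25 lost their call, 7 gained one and 15 changed sign. Of the list results 454 were kept, 7 lost their call, 2 gained one and 9 changed sign. Where no cause is given, the cause was not tested. Depth of 10129672 to 18361206 fragments limits the genes near the floor, such as cel61A and amy13A on glucose.

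Median-of-ratios scaling, which centres the fold changes by construction, gave 2977 higher and 2916 lower genes in gClrBID on glucose in place of 1493 and 4797. For the creA deletion it gave 3208 and 3078 in place of 1860 and 4751, and 717 and 738 in place of 475 and 1236 at 2-fold. For gClrBID against the creA deletion it gave 2752 and 3136 in place of 4412 and 1737. Genes higher in both strain effects on cellulose became 1718, and for the glucose effect beside the carbon response 1260 were higher and 1180 lower in both. Voom weights with the same scaling gave 3001 and 2826 for gClrBID on glucose (701 higher at 2-fold), 3232 and 3089 for the creA deletion (852 higher at 2-fold), and 2775 and 3154 for gClrBID against the creA deletion (782 lower at 2-fold). They gave 351 induced genes raised 2-fold, 1721 genes higher in both strain effects on cellulose, and 1224 higher and 1215 lower in both the glucose effect and the carbon response.

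At a minimum of 2-fold the overlaps of the strain effects on cellulose were 104, 303 and 111 (higher, lower, opposite), and of the glucose effect with the carbon response 203, 422 and 429, as fewer genes are called. Without a fold minimum 3300 induced genes were below M12 on cellulose, as more genes count as induced. The induced genes lowered 2-fold numbered 608 with a pseudocount of 0.1 and 594 with voom weights.

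Signs changed mostly for values near 0. For amy13A (PDE_01201), gClrBID against M12 on cellulose became 0.0133 with median-of-ratios scaling, 0.0182 as TPM and 0.00795 with voom and that scaling. Leaving out 1 library gave -0.147 to 0.0975. PDE_02736 in the creA deletion became 0.0236 with median-of-ratios scaling and 0.0231 with voom and that scaling. xlnR (PDE_07674) in the creA deletion became -0.0411 as TPM and ranged from -0.0132 to 0.0326 without 1 library. brlA (PDE_00087) in glucose ranged from -0.0859 to 0.203 without 1 library. The interaction of cel61A (PDE_05633) became -0.88 with voom and -1.13 with voom and scaling. Its glucose values rest on 0 to 7 fragments, and whether this caused the change was not tested. The zinc cluster list in the creA deletion changed direction with adjusted p = 0.974 (minimum of 5 FPKM), 0.818 (median-of-ratios), 0.996 (pseudocount 0.1), and ranged from 0.934 to 0.983 without 1 library. Median-of-ratios scaling also turned the beta-glucosidases in cellulose against glucose in gClrBID and the zinc cluster factors in gClrBID on glucose against M12 on cellulose, each with adjusted p = 0.996.

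No pairing of the samples by replicate number was seen. Deviations of same-numbered libraries correlated from -0.0968 to 0.0879 over 30 pairs, and 3 of 15 libraries matched best with their own number. No chance value was computed for either, so a weak pairing is not excluded. With a replicate block the zinc cluster list in the creA deletion changed direction (adjusted p = 0.999978). The block lost the brlA interaction (adjusted p = 0.0547) and no other call among the fixed genes and lists.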

Other observations

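The tests in this part were chosen after some of the values had been seen. Some genes with neighbouring locus tags changed together. Tag order is taken here as an order along the genome, which the sources used here do not give. Runs of at least 4 consecutive tags, all changed at least 2-fold in the same direction, numbered 20 for gClrBID on glucose, 12 for gClrBID on cellulose, 28 for the creA deletion on cellulose and 72 for cellulose against glucose in M12. In the same order, they held 88 of the 1771, 69 of the 872, 164 of the 1711 and 363 of the 3587 genes changed at least 2-fold. With the changes shuffled over the tags 200 times, the means were 2.86, 0.08, 2.14 and 18.8 runs and the highest counts 9, 1, 6 and 28. Chance order of the tags is therefore argued against in each (permutation test of the tags, p = 0.005 each, the smallest that the shuffles can give). Genes of shared function or sequence that lie side by side may give such runs, which was not tested.

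The run from PDE_00789 to PDE_00811, 23 tags, was chosen for its length after the values were seen. It rose both on cellulose in M12 (median log2 fold change 3.65, range 1.30 to 5.86) and further in the creA deletion on cellulose (median 3.41, range 1.71 to 4.45). Other runs that rose on cellulose in M12 went either way in the deletion. PDE_09999 to PDE_10010 rose in both (medians 3.48 and 3.81). PDE_08904 to PDE_08908 rose in M12 (3.57) and fell in the deletion (-2.57), as did PDE_09098 to PDE_09101 (6.68 and -2.50). The tags carry no names in the sources used here.

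Of the 202 tested genes with a mean under 1 FPKM in M12 on both carbon sources, 10 were called at least 2-fold higher and reached 10 FPKM in gClrBID on glucose, 12 in gClrBID on cellulose and 16 in the creA deletion. Since a tested gene had to reach 1 FPKM in at least 3 libraries, such genes could enter through the strains in which they were high. The 202 are therefore not all genes low in M12, and the counts give no share of those. The genes raised at least 2-fold by gClrBID on both carbon sources numbered 98, and 49 of these were also raised at least 2-fold in the creA deletion. 27 genes rose at least 2-fold in gClrBID on glucose and fell at least 2-fold on cellulose, and 71 did the opposite, again without numbers for independent lists.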
